A study of Mus musculus with 2 samples.

How the data were processed

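The series holds 2 single-cell RNA sequencing libraries of mouse abdominal aorta, 1 from control and 1 from the angiotensin II model of abdominal aortic aneurysm (AAA). Per the labels' protocols, the tissue was digested with collagenase and DNase, dead and red cells were removed, and 10x Chromium 3' libraries were sequenced on an Illumina NovaSeq. The extraction text of the labels speaks of carotid arteries while the tissue labels say abdominal aorta, and the tissue labels were followed. The deposited matrices hold UMI counts per gene and barcode, per the file headers. The headers name Cell Ranger 5.0.1, and the submitters' processing notes name version 6.1.2. No genome build is stated. All 55450 feature identifiers occur in GENCODE release M21, and no coordinates are given here. A total of 217 identifiers share a symbol with another, so Aldoa was not measured in its list.

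The control matrix held 13779 barcodes and 124049985 UMIs, with a median of 7332 UMIs, 2734 genes and 1.77% mitochondrial UMIs per barcode. The AAA matrix held 14086 barcodes and 93531320 UMIs, with medians of 4165.5 UMIs, 1817.5 genes and 3.44%. Barcodes with fewer than 500 genes (871 in control and 823 in AAA) or more than 20% mitochondrial UMIs (559 and 662) were removed. Scrublet scores from scanpy ranked the barcodes, and those with the highest scores were removed at 0.8% per 1000 barcodes loaded (1398 and 1444). The automatic threshold of Scrublet called 675 control barcodes and 1 AAA barcode and was not used. Kept were 11287 control cells with a median of 7969 UMIs and 11372 AAA cells with a median of 5015 UMIs.

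Both libraries were clustered together without integration. Counts were scaled to 10000 UMIs per cell and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and a shared-neighbour graph went into Leiden clustering at resolution 1.0 with seed 0. Clusters were named from fixed markers of 24 classes. A cluster needed at least 3 leading markers, each at least 2-fold above the other cells and in at least 10% of cells. It stayed unnamed if its top 10 genes held more markers of another class, or if its depth was low without an own marker among them. Of 33 clusters, 25 were named, giving 14 classes. The 9 classes with at least 100 cells in each library were compared, with 4 as main classes. Class names end in "-like" because they rest on markers alone.

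Within a class, UMIs were summed over cells and scaled to the class total (CPM). Log2 ratios for ranking genes and for lists used a pseudocount of 10 CPM, and the log2 ratios given for Bmp4 used none. Ratios have exact conditional binomial intervals, levels exact Poisson intervals and shares exact binomial intervals, all at 95% and for counting error only. A fold is a ratio without pseudocount. The markers, the 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. List members needed 20 UMIs over both libraries. A list's interval came from 1000 Poisson redraws, and its percentile from 10000 random lists drawn in 20 bins of level. The percentile describes these libraries and is not a test between groups. Named genes were the 12 highest and 12 lowest ratios of a main class (3 and 3 of the others) among genes with at least 50 UMIs and present in at least 5% of cells. A gene was left out as possible free RNA where its level was under 20% of that in the class with the highest level. Shares of endothelial-like cells with a mesenchymal UMI were taken after thinning each cell to 2000 UMIs, beside T-like cells. Some named genes are not reported here, and counts of named genes include them. A count of 0 was given the limit set by 3 counts.

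Recovery was tested on simulated data at the depth of each main class, with 200 genes changed. All were found in the right direction at 4-fold, and at least 99% at 2-fold. The 95% intervals held the true value for 92% to 98% of changed genes. The counts were drawn from Poisson distributions without spread between libraries and without free RNA. This checks the calculation only, not the ratios of the real libraries. Clustering and naming were tested on 5400 simulated cells of the 9 classes. All 18 clusters found held cells of 1 class, and 83.4% of cells received the right name. In that test, control T-like cells were named as another lymphocyte class, a pericyte cluster was named smooth muscle-like, and a dendritic cluster stayed unnamed. The simulated cells were drawn at 2000 UMIs from the pooled profile of each class and library, without other spread between cells, free RNA or doublets. Those classes came from the same clustering and naming. Pure clusters were thus largely built in, and the result does not show that the real clusters are pure.

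The alternatives covered clustering resolution (0.5 and 2.0), separate clustering, no removal of doublets, at most 10% mitochondrial UMIs, and at least 200 or 1000 genes per cell. They also covered median-of-ratios scaling, equal weight for each cell, pseudocounts of 1 and 50, all list members with any UMI, and thinning to 1000 UMIs or none. The thresholds for naming clusters were set with the data in hand. Naming clusters by markers alone and comparing single clusters were added after the data had been seen. No test between groups was made, because each group had 1 library. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.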

Results

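Cells of the mouse abdominal aorta were compared between 1 control library and 1 library from the angiotensin II model of abdominal aortic aneurysm (AAA). The questions were which cell classes each library held, where the growth factor Bmp4 was found, and which genes of endothelial-to-mesenchymal transition (EndoMT), matrix and inflammation differed within a class. Each group had 1 library, so no test between groups was possible and library and condition could not be told apart. The labels give no number of animals per library. All 95% intervals reflect counting error only. Values after a gene are its levels in the control and then the AAA library, in CPM, which are UMIs scaled to the class total. A list's median log2 ratio of AAA to control is followed by its counting interval and its percentile among 10000 random lists of genes matched for level.

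Endothelial-like cells, which line blood vessels, made up 19.5% (95% interval 18.7 to 20.2; 2198 cells) of the control library and 5.65% (5.24 to 6.09; 643 cells) of the AAA library. The markers do not tell the lining of the aorta from that of small vessels, so these shares are not those of the aortic lining. Within this class, cluster 3 made up 15.5% and 0.185% of the libraries and cluster 17 made up 2.51% and 0.888%. Fibroblast-like cells, the matrix-producing cells of the outer wall, made up 42.2% (95% interval 41.3 to 43.1; 4760 cells) of the control library and 19.5% (18.7 to 20.2; 2212 cells) of the AAA library. Smooth muscle-like cells, the contractile cells of the media, made up 4.33% (95% interval 3.96 to 4.72; 489 cells) of the control library and 13.2% (12.6 to 13.8; 1499 cells) of the AAA library. The ratios of AAA to control shares were 0.290 (0.266 to 0.317) for endothelial-like, 0.461 (0.438 to 0.485) for fibroblast-like and 3.04 (2.75 to 3.38) for smooth muscle-like cells. Clustering each library on its own moved the fibroblast-like ratio to 0.737. The kept cells had medians of 7969 UMIs in the control and 5015 UMIs in the AAA library, a gap in depth that stands beside every share.

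Neutrophil-like cells, phagocytes of acute inflammation, made up 0.425% and 3.42% of the control and AAA libraries, a ratio of 8.04 (5.95 to 11.1). B-like cells, the antibody-lineage lymphocytes, made up 2.55% and 0.141%, a ratio of 0.0551 (0.0311 to 0.0911), and T-like cells 2.98% and 1.35%, a ratio of 0.455 (0.373 to 0.552). Macrophage-like cells made up 13.5% and 12.6%, a ratio of 0.938 (0.872 to 1.01), which turned to between 1.17 and 1.51 under 6 other settings. Lymphatic endothelial-like cells had a ratio of 0.523 (0.422 to 0.645), conventional dendritic-like cells 1.23 (1.04 to 1.45), pericyte-like cells 0.937 (0.763 to 1.15) and Schwann-like cells 1.01 (0.845 to 1.22). Mesothelial-like cells, the outer lining of serous surfaces, numbered 176 in the control library and 0 in the AAA library, where 3 counts set an upper limit of 0.0264%.

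For endothelial-like, fibroblast-like, macrophage-like and Schwann-like cells, different clusters held most of the class in the 2 libraries. Endothelial-like cells were mostly cluster 3 in the control library (1752 and 21 cells in control and AAA) and cluster 11 in the AAA library (163 and 521 cells), and cluster 17 had 283 and 101 cells. Fibroblast-like cells of the AAA library were mostly cluster 0 (40 and 2153 cells), and those of the control library lay in clusters 1, 5 and 8, each with at most 24 AAA cells. Smooth muscle-like cells were mostly cluster 2 in both libraries (331 and 1485 cells), with cluster 27, which also led in 5 pericyte markers, at 158 and 14 cells. Macrophage-like cells were mostly cluster 7 in the control library (1097 and 10 cells) and cluster 6 in the AAA library (101 and 1192 cells). Schwann-like cells were mostly cluster 25 in the control library (142 and 38 cells) and cluster 20 in the AAA library (99 and 208 cells). A cluster that is mostly of 1 library may be that library and not a cell type. Some genes given below led clusters held mostly by 1 library, so their ratios follow how cells were divided between clusters. For the control library these were Car4, Tcf15, Aqp7, Cyp1a1 and Timp4 (cluster 3), Penk, Cxcl13, Inmt and Agt (cluster 1), Clec3b (cluster 5), Smpd3 (cluster 8), Cd163, Folr2, Cd209f, Fcna and Ccl24 (cluster 7), Lyz1 and Retnla (cluster 22), and Actc1, Kcnk3, Notch3 and Vtn (cluster 27). For the AAA library they were Fam167b and Lrg1 (cluster 11), Comp, Mmp3, Mfap4 and Col11a1 (cluster 0), Trem2 and Cd72 (cluster 6), and Mki67 (cluster 23). Unnamed clusters made up 3.88% and 35.9% of the libraries, the bulk of them clusters 4, 9 and 10 in the AAA library. AAA cells of cluster 4, 14.7% of the library, had medians of 1435 UMIs and 6.36% mitochondrial UMIs, and the cluster led in no marker. The AAA cells of cluster 10 had a median of 1594 UMIs. All unnamed cells count in the total of kept cells, so they lower the AAA share of every named class. Cluster 18, at 0.106% and 3.11% of cells, led in 7 of 8 endothelial markers. It stayed unnamed because its top 10 genes held Kit, a single marker of the mast cell list, and none of the endothelial list. Its 354 AAA cells are thus outside all endothelial-like values. Cluster 24, which led in 8 endothelial markers, made up 1.59% and 0.0967% of cells, and cluster 10, which led in 6 macrophage markers, 0.115% and 7.28%, and both stayed unnamed for low depth without an own marker among their top genes. The plot of shares shows all named classes.

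**Figure D1:**
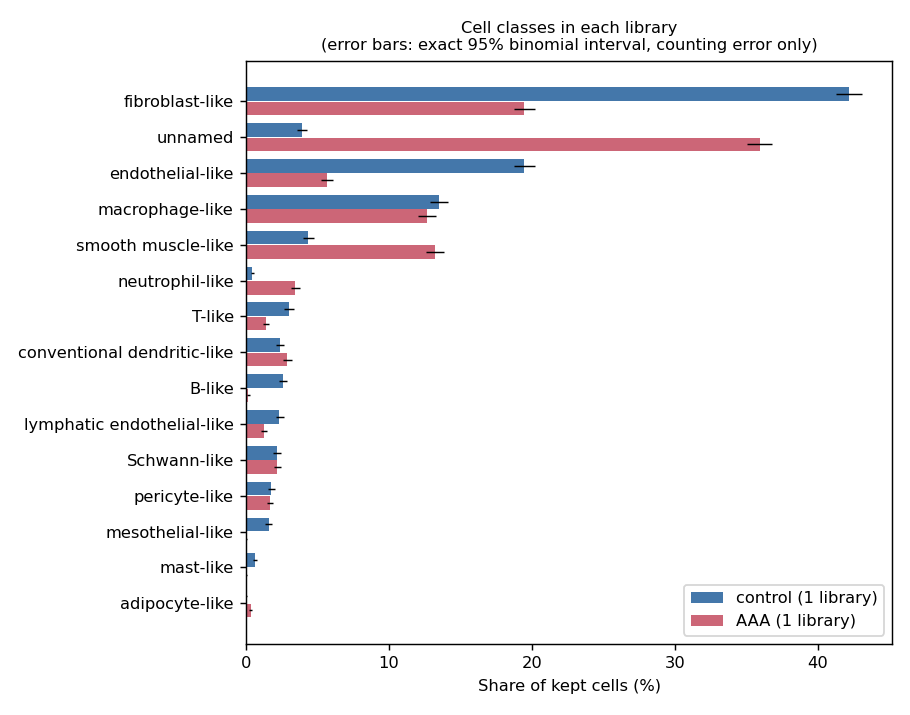
Share of kept cells in percent per named class in the control and AAA libraries, with exact binomial 95% intervals as bars. Endothelial-like cells stand at 19.5% in control and 5.65% in AAA, and smooth muscle-like cells at 4.33% and 13.2%.

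Bmp4 (ENSMUSG00000021835), a secreted growth factor of the bone morphogenetic protein family, stood at 77.3 CPM in all control cells and 59.1 CPM in all AAA cells, 1.31-fold lower (95% interval 1.26 to 1.35). In endothelial-like cells it stood at 268 and 139 CPM, 1.92-fold lower (95% interval 1.76 to 2.11). In fibroblast-like cells it stood at 53.1 and 101 CPM, 1.90-fold higher (95% interval 1.79 to 2.01), which compared control cells mostly of clusters 1, 5 and 8 with AAA cells mostly of cluster 0. Smooth muscle-like cells held 14.5 and 7.09 CPM, 2.04-fold lower (95% interval 1.55 to 2.68), and macrophage-like cells 4.19 and 3.32 CPM. In smooth muscle-like cluster 2 alone it stood at 7.18 and 7.07 CPM, a ratio of 0.984 (0.670 to 1.48), and in control cells of cluster 27 at 31.0 CPM. T-like cells, which are not known to make it, held 8.50 and 8.47 CPM, the latter on 3 UMIs (95% interval 1.75 to 24.7). In CPM, the macrophage-like, cluster 2 and AAA smooth muscle-like levels thus did not stand clearly above free RNA. Control cluster 27, at 31.0 CPM (24.0 to 39.4), stood above control T-like cells (4.76 to 14.0). A Bmp4 UMI was in 16.2% of control smooth muscle-like and 4.17% of control T-like cells, at median depths of 14467 and 5113.5 UMIs. In the AAA library these shares were 6.60% and 1.95%, at median depths of 10398 and 2183.5 UMIs. With depths so unlike, neither CPM nor shares settle whether AAA smooth muscle-like Bmp4 was free RNA.

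Within the endothelial-like clusters Bmp4 was highest in cluster 17, at 1316 and 530.5 CPM, 2.48-fold lower (95% interval 2.24 to 2.75). Cluster 11 held 212 and 44.0 CPM, 4.81-fold lower (95% interval 3.90 to 5.96), and cluster 3 held 13.4 CPM in the control library. Cluster 17 held 49.8% of all Bmp4 UMIs of the control library and 8.61% of those of the AAA library. Unnamed clusters held 0.310% and 45.0% of the libraries' Bmp4 UMIs, of which AAA cluster 9 held 25.0% and AAA cluster 18 held 14.5%. Fibroblast-like cells held 33.9% and 39.0%. In the control library the fibroblast-like clusters 1, 8, 5 and 0 held 27.4, 36.2, 139.6 and 162.5 CPM. Cluster 0, with 40 control cells, held 162.5 and 102 CPM, 1.59-fold lower (95% interval 1.30 to 1.93), the opposite direction to the fibroblast-like class. Lymphatic endothelial-like cells held 84.6 and 15.5 CPM and Schwann-like cells 6.81 and 18.04 CPM. Pericyte-like cells held 3.66 and 8.25 CPM and conventional dendritic-like cells 2.82 and 5.78 CPM.

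Without removal of doublets the log2 ratio of Bmp4, taken without a pseudocount, turned from -0.94 to 0.35 in endothelial-like cells and from -1.03 to 0.15 in smooth muscle-like cells, and the cluster that overlapped most with cluster 17 was then unnamed. With a pseudocount of 10 CPM the main values were -0.90 and -0.52. At resolution 0.5 the cluster that overlapped most with cluster 17 held 295 control and 440 AAA cells, a different mix with a Jaccard overlap of 0.522, and a log2 ratio of -3.08. At resolution 2.0 the cluster that overlapped most with cluster 11, with 94 and 512 cells, had -0.48. The log2 ratio stood at -0.05 in smooth muscle-like cells at resolution 0.5.

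**Figure D2:**
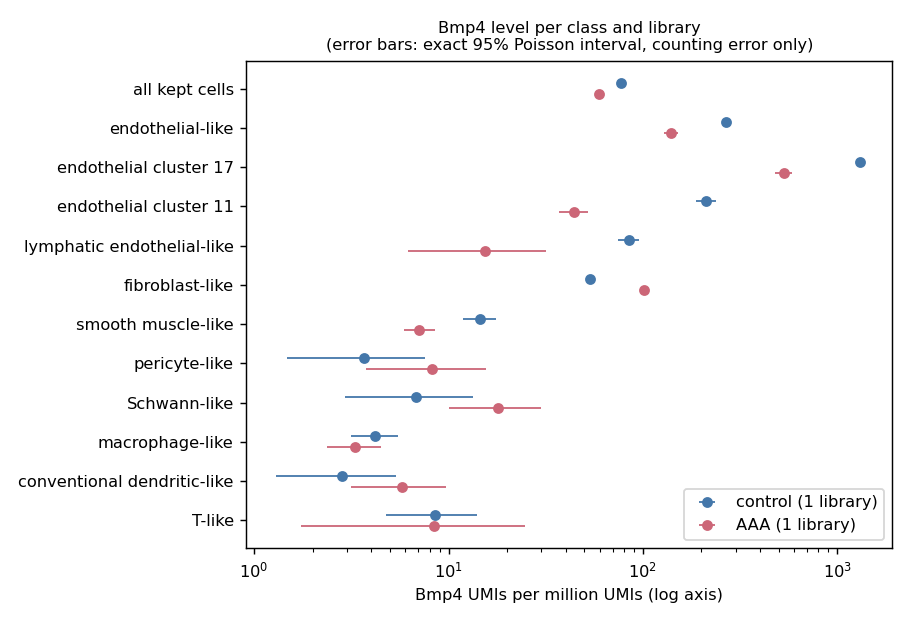
Bmp4 in CPM (log axis) per class in the control and AAA libraries, with Poisson 95% intervals as bars. Endothelial-like cells stand at 268 CPM in control and 139 CPM in AAA, and fibroblast-like cells at 53.1 CPM and 101 CPM.

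BMP target genes, the Id and inhibitory Smad genes that BMP receptors switch on, were lower in endothelial-like cells of the AAA library, with 0 of 8 members at least 2-fold higher and 5 at least 2-fold lower and a median of -0.93 (-1.03 to -0.83, percentile 0.01). Id1 (ENSMUSG00000042745), an inhibitor of differentiation, stood at 809 and 279 CPM, 2.90-fold lower (95% interval 2.72 to 3.09). The others at least 2-fold lower included Smad6 (57.1 and 22.7 CPM), Hey1 (48.3 and 19.6 CPM) and Atoh8 (46.8 and 9.43 CPM). Within clusters 11 and 17 the list medians were -0.62 and -0.56, but Id1 was higher in cluster 17, at 179.8 and 295 CPM, a ratio of 1.64 (1.40 to 1.92). Fibroblast-like cells had a median of 0.35 (0.27 to 0.40, percentile 99.7) with Smad7 (34.7 and 102 CPM) and Id2 (183 and 82.3 CPM). AAA T-like cells held 669 CPM of Smad7, but AAA Schwann-like cells held 55.3 and AAA pericyte-like cells 116 CPM. The T-like level of Smad7 was thus not a general free RNA level. Smooth muscle-like cells had a median of -0.51 (-0.60 to -0.43, percentile 0.05), and macrophage-like cells 0.21 (0.07 to 0.33, percentile 97.05), the last turning to -0.17 without removal of doublets.

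BMP ligands had medians of -0.05 (-0.16 to 0.05, percentile 47.21) in endothelial-like, -0.33 (-0.39 to -0.27, percentile 0.25) in fibroblast-like, -0.50 (-0.58 to -0.34, percentile 0.06) in smooth muscle-like and -0.21 (-0.30 to -0.11, percentile 16.44) in macrophage-like cells. In cluster 17 alone the ligand median was -1.26, and in cluster 6 alone it turned to 0.22 (-0.09 to 0.53). In endothelial-like cells, Bmp6 (243 and 60.2 CPM) and Bmp2 (2.05 and 19.1 CPM) lay on opposite sides. The smooth muscle-like median turned to 0.07 without removal of doublets. BMP receptors and Smads had medians of -0.23 (-0.33 to -0.08, percentile 3.56), -0.02 (-0.07 to 0.03, percentile 55.81), -0.21 (-0.28 to -0.11, percentile 6.2) and -0.23 (-0.32 to -0.14, percentile 19.26) in the same order. BMP antagonists had medians of -0.0049 (-0.07 to 0.11, percentile 35.38), -0.41 (-0.43 to -0.38, percentile 0.53), -0.17 (-0.22 to -0.13, percentile 9.78) and 0.09 (0.01 to 0.19, percentile 85.5). The smooth muscle-like antagonist median turned to 0.05 at resolution 0.5 and to 0.11 (-0.02 to 0.26) in cluster 2 alone, and the macrophage-like one to -0.18 without removal of doublets. Among antagonists in fibroblast-like cells, Mgp (2133 and 26249.6 CPM), the matrix Gla protein that binds BMPs, was 12.3-fold higher (95% interval 12.2 to 12.4), and Fst (364 and 143 CPM), an activin binder, was 2.55-fold lower (95% interval 2.44 to 2.65). Mgp also stood at 5714 CPM in T-like cells of the AAA library.

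The TGF-beta pathway, the receptor and ligand system that drives matrix genes, was higher on balance in the AAA library in each main class. Its medians were 0.48 (0.36 to 0.59, percentile 99.97) in endothelial-like, 0.33 (0.26 to 0.41, percentile 99.75) in fibroblast-like, 0.25 (0.15 to 0.33, percentile 99.93) in smooth muscle-like and 0.27 (0.13 to 0.42, percentile 97.82) in macrophage-like cells, the last turning to -0.17 without removal of doublets. In endothelial-like cells Ccn2 (43.4 and 231 CPM), the connective tissue growth factor, was counted as at least 2-fold higher, but T-like cells of the AAA library held 226 CPM, and within cluster 11 it stood at 202 and 208 CPM.

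Endothelial-like cells of the AAA library held more UMIs of mesenchymal genes, the contractile and collagen genes counted as a sign of EndoMT, with 10 of 12 members at least 2-fold higher and 0 at least 2-fold lower and a median of 1.40 (1.36 to 1.45, percentile 100). Acta2 (ENSMUSG00000035783), the smooth muscle actin, stood at 149.9 and 682 CPM, 4.55-fold higher (95% interval 4.31 to 4.81), and Col1a1 (147 and 561 CPM) and Vim (1051 and 3324 CPM) were higher as well. T-like cells of the AAA library, which should lack Acta2 and Col1a1, held 1174 CPM of Acta2 and 1267 CPM of Col1a1, above the endothelial-like levels, and 1464 CPM of Vim, which T cells express. The list medians within clusters 11 and 17 were 1.52 and 0.98.

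With cells thinned to 2000 UMIs, 67.3% (63.1 to 71.2) of 538 endothelial-like and 82.6% (72.9 to 89.9) of 86 T-like cells of the AAA library had an Acta2 UMI. The median depths before thinning were 4274 and 2183.5 UMIs, and the unthinned shares were 93.5% and 89.6%. In the control library the thinned Acta2 shares were 23.6% of 2078 endothelial-like and 21.5% of 297 T-like cells, with median depths of 5745 and 5113.5 UMIs and unthinned shares of 52.8% and 49.4%. For Col1a1 the thinned shares in the AAA library were 67.8% of endothelial-like and 83.7% of T-like cells, for Tagln 46.3% and 68.6%, for Cnn1 11.5% and 17.4%, and for Col3a1 77.1% and 94.2%. Fn1 was in 60.2% and 65.1%, and Vim in 91.3% and 88.4%. For Acta2, Tagln, Cnn1, Col1a1 and Col3a1 the thinned shares in endothelial-like cells of the AAA library thus did not exceed those in T-like cells, the shallower class. Without thinning, AAA endothelial-like cells held 4.16 Acta2 UMIs per cell and T-like cells 2.70. The difference in thinned Acta2 share between the classes, -15.3 percentage points, turned to 3.86 without thinning. In the control library Fn1 was in 27.9% of endothelial-like and 17.5% of T-like cells, and that difference turned to -3.08 percentage points without removal of doublets.

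The number of Acta2 UMIs per Myh11 UMI in the AAA library was 3.47 (3.45 to 3.49) in smooth muscle-like and 4.57 (3.64 to 5.80) in T-like cells. It was 4.97 (4.44 to 5.57) in endothelial cluster 11, 11.2 (8.66 to 14.8) in endothelial cluster 17 and 31.0 (28.2 to 34.2) in the unnamed cluster 18. Control cluster 17 had 11.9 (9.39 to 15.2).

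**Figure D3:**
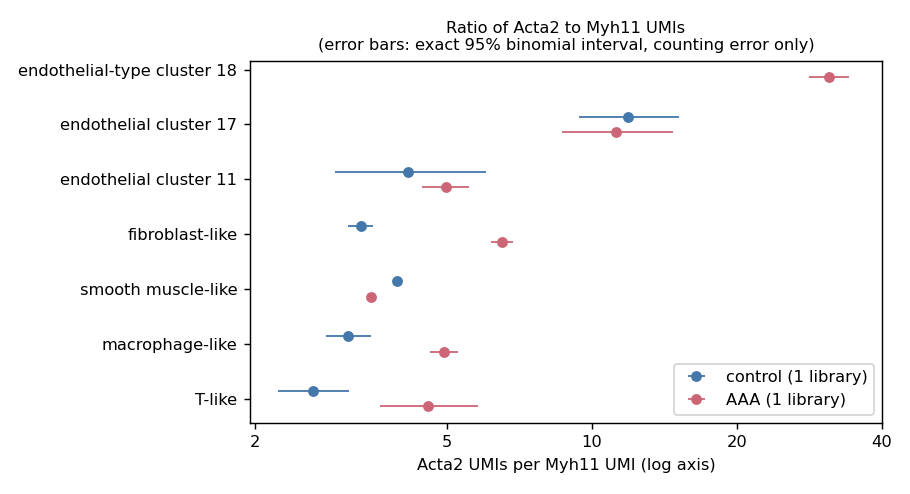
Acta2 UMIs per Myh11 UMI (log axis) per class or cluster and library, with binomial 95% intervals as bars. In the AAA library, T-like cells stand at 4.57 and cluster 18 at 31.0.

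Endothelial identity genes, the junction and receptor genes of all vessels, differed little, with 0 of 10 members at least 2-fold higher and 1 at least 2-fold lower and a median of -0.10 (-0.16 to -0.04, percentile 28.9). The members Pecam1, Cdh5, Tie1, Kdr and Cldn5 were also markers that named the class, so cells that had lost them could have stayed outside it. Pecam1 stood at 1617 and 1596 CPM, and Kdr, the main VEGF receptor, at 1836 and 660.3 CPM, 2.78-fold lower (95% interval 2.67 to 2.90). Kdr was within 2-fold in cluster 11, a ratio of 0.765 (0.716 to 0.817), and higher in cluster 17, at 13.1 and 39.9 CPM. EndoMT transcription factors had a median of 0.03 (-0.10 to 0.17, percentile 64) and of -0.38 in cluster 17 alone, with Snai1 (5.90 and 22.7 CPM) and Twist1 (42.7 and 10.2 CPM) at least 2-fold higher and lower, Twist1 with a ratio of 0.876 (0.273 to 3.27) in cluster 11. Adhesion and activation genes, which capture leukocytes, had 4 of 9 members at least 2-fold higher and 0 at least 2-fold lower and a median of 0.53 (0.31 to 0.74, percentile 99.88). Among them, Sele (4.16 and 55.6 CPM), Selp (54.6 and 269 CPM) and Ackr1 (5.78 and 89.7 CPM) were higher, with Sele, the E-selectin, 13.4-fold higher (95% interval 10.2 to 17.8). In cluster 11 alone Ackr1 stood at 63.2 and 116 CPM, a ratio of 1.84 (1.45 to 2.37).

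Basement membrane genes in endothelial-like cells had a median of 0.68 (0.57 to 0.77, percentile 99.95) with Col15a1 (88.0 and 429.6 CPM) and Nid2 (15.5 and 107 CPM), and fibrillar collagens 1.22 (1.15 to 1.28, percentile 100). Of the collagens, Col1a1, Col1a2 and Col3a1 stood at 561, 622 and 745 CPM in AAA endothelial-like cells, below the 1267, 1473 and 1696 CPM of AAA T-like cells. Per cell, however, AAA endothelial-like cells held 3.42 Col1a1 UMIs and the shallower AAA T-like cells 2.92. The CPM levels alone thus do not settle whether these collagen UMIs were free RNA. The interferon response had 1 of 12 members at least 2-fold higher and 7 at least 2-fold lower and a median of -1.01 (-1.09 to -0.89, percentile 0), with Cxcl9 (341 and 14.5 CPM) and Isg15 (243 and 104 CPM) lower and Cxcl10 (7.05 and 97.6 CPM) higher. T-like cells held 24.4 and 164 CPM of Cxcl10, above the endothelial-like levels. AAA Schwann-like cells held 161 CPM of Cxcl10 and AAA pericyte-like cells 12.8 CPM, so its free RNA level stayed uncertain. Proliferation genes had a median of 0.61 (0.45 to 0.69, percentile 100) with 6 of 11 members at least 2-fold higher and 0 at least 2-fold lower. The interferon medians were -0.30 in cluster 11 and -0.17 in cluster 17 alone. MHC class II had a median of -0.25 (-0.32 to -0.14, percentile 4.24), turning to 0.62 without removal of doublets, renin-angiotensin genes -0.22 (-0.33 to -0.14, percentile 3.72) and hypoxia and glycolysis genes 0.22 (0.12 to 0.36, percentile 92.86).

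Beyond the lists, the highest named genes in endothelial-like cells of the AAA library included Lrg1 (ENSMUSG00000037095), a secreted angiogenic glycoprotein, at 66.9 and 959 CPM, 14.3-fold higher (95% interval 13.4 to 15.3). Others were Fam167b (22.1 and 442 CPM), Mmp14 (17.6 and 203 CPM), Insr (33.1 and 299 CPM) and Igfbp3 (56.8 and 432 CPM), with Mmp14 a membrane matrix metalloproteinase and Insr the insulin receptor. Among the lowest was Cyp1a1, a target of the aryl hydrocarbon receptor, at 201 and 0.765 CPM, 263-fold lower (95% interval 89.8 to 1275). The inhibitor Timp4 (852 and 43.1 CPM), the carbonic anhydrase Car4 (456 and 21.4 CPM), the water and glycerol channel Aqp7 (308 and 14.3 CPM) and the transcription factor Tcf15 (674 and 47.7 CPM) were also lower, as were the cell cycle inhibitors Cdkn1c (731 and 48.7 CPM) and Cdkn1a (592 and 65.8 CPM). In cluster 11 alone, all 12 higher and all 12 lower named genes kept their direction, but many ratios were smaller, with Lrg1 at 749.9 and 1152 CPM, 1.54-fold higher (95% interval 1.43 to 1.65), and Cdkn1c at 107 and 45.0 CPM, 2.37-fold lower (95% interval 1.86 to 3.02). In cluster 17 alone 10 of 12 and 9 of 12 did, some on few UMIs, with Ackr1 at 0 and 3 UMIs and Timp4 at 20.7 and 21.9 CPM there.

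Smooth muscle-like cells of the AAA library held similar levels of contractile genes, with 0 of 13 members at least 2-fold higher and 0 at least 2-fold lower and a median of 0.09 (0.08 to 0.11, percentile 87.29). Myh11 (6123 and 6527 CPM) and Acta2 (24166 and 22660.2 CPM) are examples. The list members Myh11, Cnn1, Acta2, Tagln, Lmod1, Smtn, Actg2 and Des were also the markers that named the class. Cells that had lost them could have stayed outside the class, so the list cannot show such a loss. Genes of smooth muscle modulation, the shift from contraction to matrix and inflammatory genes, had 8 of 12 members at least 2-fold higher and 1 at least 2-fold lower and a median of 1.64 (1.55 to 1.70, percentile 100). Fn1 (1476 and 5293 CPM), fibronectin, was 3.59-fold higher (95% interval 3.51 to 3.66) against 686 CPM in AAA T-like cells, and Mgp (4930.0 and 16108 CPM), Vcam1 (21.5 and 108 CPM) and Tnfrsf11b (12.8 and 38.3 CPM) were higher too. Spp1, Lgals3 and Lum, also counted as higher, stood below the T-like levels of 626, 556 and 525 CPM in the AAA library. The median depths there were 10398 UMIs in smooth muscle-like and 2183.5 UMIs in T-like cells. CPM alone thus does not settle whether the UMIs of these 3 genes were free RNA. Klf4, a transcription factor, was lower at 182 and 82.1 CPM. The modulation median moved to 0.97 with a pseudocount of 50.

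Elastic fibre genes, which give the aorta its recoil, had a median of -0.0034 (-0.04 to 0.06, percentile 72.71) in smooth muscle-like cells, with Eln, the elastin gene, at 3810.0 and 1806 CPM, 2.11-fold lower (95% interval 2.08 to 2.14). Cluster 2 alone held 4917 and 1812 CPM of Eln. Matrix proteases and inhibitors had 5 of 16 members at least 2-fold higher and 3 at least 2-fold lower and a median of 0.31 (0.22 to 0.40, percentile 100), with the aggrecanases Adamts4 (26.0 and 1.24 CPM) and Adamts5 (130.4 and 50.3 CPM) lower in the class. In cluster 2 alone Adamts4 stood at 0.820 and 1.19 CPM. Fibrillar collagens had a median of 0.24 (0.15 to 0.33, percentile 98.05) and basement membrane genes 0.18 (0.14 to 0.22, percentile 97.14). Renin-angiotensin genes had a median of -0.32 (-0.39 to -0.16, percentile 0.73), turning to 0.13 (-0.05 to 0.32) in cluster 2 alone, with Ace at 36.4 and 84.3 CPM. Nr4a1, at 220.0 and 28.1 CPM, is also a member of the immediate early list, which was lower in all 9 compared classes. Stromal chemokines and cytokines had a median of -0.48 (-0.63 to -0.35, percentile 0), which turned to 0.25 at resolution 0.5, to 0.22 without removal of doublets and to 0.28 in cluster 2 alone. The interferon response had a median of -0.31 (-0.36 to -0.13, percentile 0.34), turning to 0.16 without removal of doublets and 0.23 in cluster 2 alone, hypoxia and glycolysis 0.19 (0.12 to 0.25, percentile 99.51) and proliferation 0.07 (-0.01 to 0.13, percentile 97.38).

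Named genes higher in smooth muscle-like cells of the AAA library included the metal-binding genes Mt1 (309 and 1934 CPM) and Mt2 (40.5 and 398 CPM), the growth factor binder Igfbp2 (57.0 and 304 CPM) and the sarcomere gene Tcap (76.6 and 356 CPM). Dbp (ENSMUSG00000059824), a circadian transcription factor, stood at 20.5 and 266 CPM, and the clock gene Per3 stood at 4.12 and 69.4 CPM. Among lower genes, Notch3, a mural cell receptor, stood at 279.5 and 24.5 CPM, 11.4-fold lower (95% interval 10.3 to 12.7), and in cluster 2 alone at 56.4 and 19.3 CPM, 2.92-fold lower. The matrix protein Vtn, at 139.7 and 3.07 CPM in the class, had 1 and 2 UMIs in cluster 2. Fst, Actc1, Cpxm2 and Kcnk3 were lower in the class but turned in cluster 2 alone, and they were the 4 of the 96 named genes of the main classes that turned under any of 8 alternatives. At resolution 0.5 their log2 ratios were 1.12, 2.40, 1.95 and 0.71. The median log2 ratio of all genes was -0.14 in smooth muscle-like cells, -0.12 in macrophage-like cells and -0.17 in cluster 6, so ratios there read relative to those shifts.

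Fibroblast-like cells of the AAA library held more myofibroblast RNA, the matrix and contractile genes of scar-forming fibroblasts, with 9 of 10 members at least 2-fold higher and 0 at least 2-fold lower and a median of 2.42 (2.37 to 2.47, percentile 100). Comp (ENSMUSG00000031849), a cartilage and tendon matrix protein, was 25.7-fold higher (95% interval 24.7 to 26.8) at 51.6 and 1327 CPM, and Ltbp2 (12.8 and 469 CPM), Cthrc1 (12.3 and 103 CPM), Tnc (1.29 and 42.2 CPM) and Postn (251 and 517 CPM) were higher too. Fn1 (1925 and 1674 CPM) was not higher, and Acta2 (97.6 and 599.9 CPM) stood below the 1174 CPM of AAA T-like cells. Per cell, however, AAA fibroblast-like cells held 5.02 Acta2 UMIs and the shallower AAA T-like cells 2.70. Acta2 UMIs per Myh11 UMI were 6.51 (6.19 to 6.85) in AAA fibroblast-like and 4.57 (3.64 to 5.80) in AAA T-like cells. The CPM levels alone thus do not settle whether fibroblast-like Acta2 was free RNA. The myofibroblast median moved to 1.69 with a pseudocount of 50. Fibrillar collagens had a median of 0.58 (0.58 to 0.59, percentile 99.48), with Col1a1 (6895 and 10344 CPM) and Col11a1 (0.565 and 146 CPM) higher and Col5a3 (153 and 38.6 CPM) lower. Basement membrane genes had 0 of 11 members at least 2-fold higher and 5 at least 2-fold lower, with a median of -0.55 (-0.59 to -0.51, percentile 0.34) and Nid1 (990.4 and 303 CPM) among the lower.

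Matrix proteases and inhibitors in fibroblast-like cells had 6 of 17 members at least 2-fold higher and 4 at least 2-fold lower and a median of 0.66 (0.63 to 0.68, percentile 100). Among them, the stromelysin Mmp3 (328 and 1631 CPM), the inhibitor Timp1 (217 and 1124 CPM) and the cathepsin Ctsk (154 and 453 CPM) were higher, and Adamts5 (556 and 208 CPM) was lower. Elastic fibre genes had a median of 0.14 (0.11 to 0.16, percentile 95.79), with Mfap4 (326 and 1195 CPM) and Fbn1 (1249 and 459.8 CPM) on opposite sides. Stromal chemokines and cytokines had a median of -0.42 (-0.50 to -0.33, percentile 0.4), with the eosinophil attractant Ccl11 (339 and 29.5 CPM) and the B cell attractant Cxcl13 (530.2 and 24.8 CPM) lower. Renin-angiotensin genes had a median of -0.39 (-0.43 to -0.35, percentile 0.08), with Agt, the angiotensinogen gene, at 79.6 and 5.40 CPM. Interferon response, MHC class II, hypoxia and glycolysis, and proliferation genes had medians of -0.39 (-0.45 to -0.31, percentile 0.03), -0.03 (-0.07 to 0.03, percentile 49.31), 0.22 (0.17 to 0.28, percentile 98.74) and 0.31 (0.24 to 0.36, percentile 100).

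Other named genes higher in fibroblast-like cells of the AAA library were the acute phase protein Saa3 (3.72 and 300.5 CPM), the Wnt antagonist Frzb (1.23 and 221 CPM), the CCN matricellular genes Ccn2 (90.2 and 887 CPM) and Ccn3 (24.0 and 511 CPM) and the circadian Dbp (10.8 and 242 CPM), the last 22.5-fold higher (95% interval 20.6 to 24.6). Lower genes included Smpd3 (303 and 2.97 CPM), Penk (832 and 39.7 CPM), Inmt (806 and 64.9 CPM), Clec3b (3867 and 396 CPM) and Lpl (1195 and 113 CPM), of which Penk encodes an opioid precursor and Lpl lipoprotein lipase. No fibroblast-like cluster held at least 100 cells in each library, so these ratios compare clusters 1, 5 and 8 of the control library with cluster 0 of the AAA library.

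Macrophage-like cells of the AAA library held less RNA of resident macrophage genes, the scavenger receptors of long-lived tissue macrophages, with 0 of 8 members at least 2-fold higher and 8 at least 2-fold lower and a median of -3.98 (-4.06 to -3.91, percentile 0). Lyve1 stood at 801 and 3.48 CPM, 229.8-fold lower (95% interval 169.9 to 319), with Cd163 (567 and 4.81 CPM), Timd4 (112 and 0.332 CPM) and Folr2 (793 and 22.6 CPM) lower as well. Genes of Trem2-type macrophages, the lipid-handling state, had 7 of 8 members at least 2-fold higher and 1 at least 2-fold lower and a median of 2.52 (2.47 to 2.57, percentile 100). Spp1 (ENSMUSG00000029304), osteopontin, was 714-fold higher (95% interval 573 to 902) at 6.37 and 4551 CPM, and Trem2 (ENSMUSG00000023992) was 11.5-fold higher (95% interval 10.7 to 12.3) at 73.2 and 840.0 CPM, while Lpl (1463 and 699 CPM) was lower. The resident median moved to -5.02 with a pseudocount of 1 and -3.12 with a pseudocount of 50. In cluster 6 alone the medians were -0.90 for resident and 0.79 for Trem2-type genes. The cluster 6 medians were -1.43 for the interferon response, -0.15 for MHC class II and 0.53 for proliferation, and the mitochondrial one turned to 0.16.

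Inflammatory cytokine genes in macrophage-like cells had 4 of 12 members at least 2-fold higher and 1 at least 2-fold lower and a median of 0.51 (0.43 to 0.54, percentile 99.97). The chemokines Ccl4 (80.0 and 669 CPM) and Ccl3 (47.5 and 193 CPM) were higher, Il1b (75.4 and 116 CPM) and Tnf (43.2 and 70.1 CPM) lay within 2-fold, and Il6 (5.00 and 0.995 CPM) was lower. Matrix proteases had 10 of 18 members at least 2-fold higher and 2 at least 2-fold lower and a median of 0.82 (0.75 to 0.89, percentile 100), with the macrophage elastase Mmp12 (82.2 and 800.2 CPM), Mmp14 (16.4 and 131 CPM) and the cathepsin Ctsl (246 and 888 CPM) higher and the gelatinase Mmp9 (224 and 3.32 CPM) lower. Recruited monocyte genes had 1 of 8 members at least 2-fold higher and 4 at least 2-fold lower and a median of -0.92 (-0.98 to -0.86, percentile 0.13), with Ccr2 (805 and 298 CPM), the receptor for monocyte recruitment, 2.70-fold lower (95% interval 2.60 to 2.81), and the median turned to 0.15 at resolution 2.0. The interferon response had a median of -0.81 (-0.90 to -0.68, percentile 0.01), with Cxcl9 (76.2 and 3.65 CPM) lower, and MHC class II -0.76 (-0.78 to -0.74, percentile 1), with its regulator Ciita (183 and 45.2 CPM). Cxcl10 stood at 43.1 and 157 CPM in macrophage-like cells, not above the 164 CPM of AAA T-like cells, and at 167 and 148 CPM in cluster 6 alone. AAA pericyte-like cells held only 12.8 CPM of Cxcl10, so the T-like level need not be free RNA. Hypoxia and glycolysis genes had a median of 0.70 (0.65 to 0.81, percentile 99.99), with 5 of 11 members at least 2-fold higher and 0 at least 2-fold lower. Proliferation genes had a median of 1.51 (1.43 to 1.57, percentile 100), with Mki67 (52.5 and 186 CPM), and cluster 23, led by cell cycle genes, had 29 and 230 macrophage-like cells.

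Other named genes higher in macrophage-like cells of the AAA library were Arg1, the arginase of alternatively activated macrophages, at 10.3 and 399 CPM, 38.6-fold higher (95% interval 32.4 to 46.4), and Cd72 (27.5 and 575 CPM), Gpnmb (60.3 and 457 CPM) and Cd9 (47.2 and 386 CPM). Retnla, another gene of alternative activation, was 428-fold lower (95% interval 384 to 478) at 11526 and 27.0 CPM, and Fcna (417 and 1.99 CPM), Ccl24 (360.3 and 1.66 CPM) and Ednrb (341 and 9.12 CPM) were lower. Lyz1 (1747 and 12.8 CPM) and Cd209f (439 and 0.498 CPM) were lower as well, and both genes have near-identical copies, which leaves their levels uncertain. In cluster 6 alone 11 of 12 higher and 12 of 12 lower named genes kept their direction, but many ratios were smaller there. Arg1 stood at 106 and 455 CPM in cluster 6, 4.31-fold higher (95% interval 3.58 to 5.22), Cd9 at 195 and 381 CPM, 1.95-fold higher, Trem2 at 227 and 877 CPM, 3.87-fold higher, and Spp1 at 44.6 and 4949 CPM, 111-fold higher. The exception, Gpnmb, stood at 605 and 505 CPM, a ratio of 0.833 (0.768 to 0.905).

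**Figure D4:**
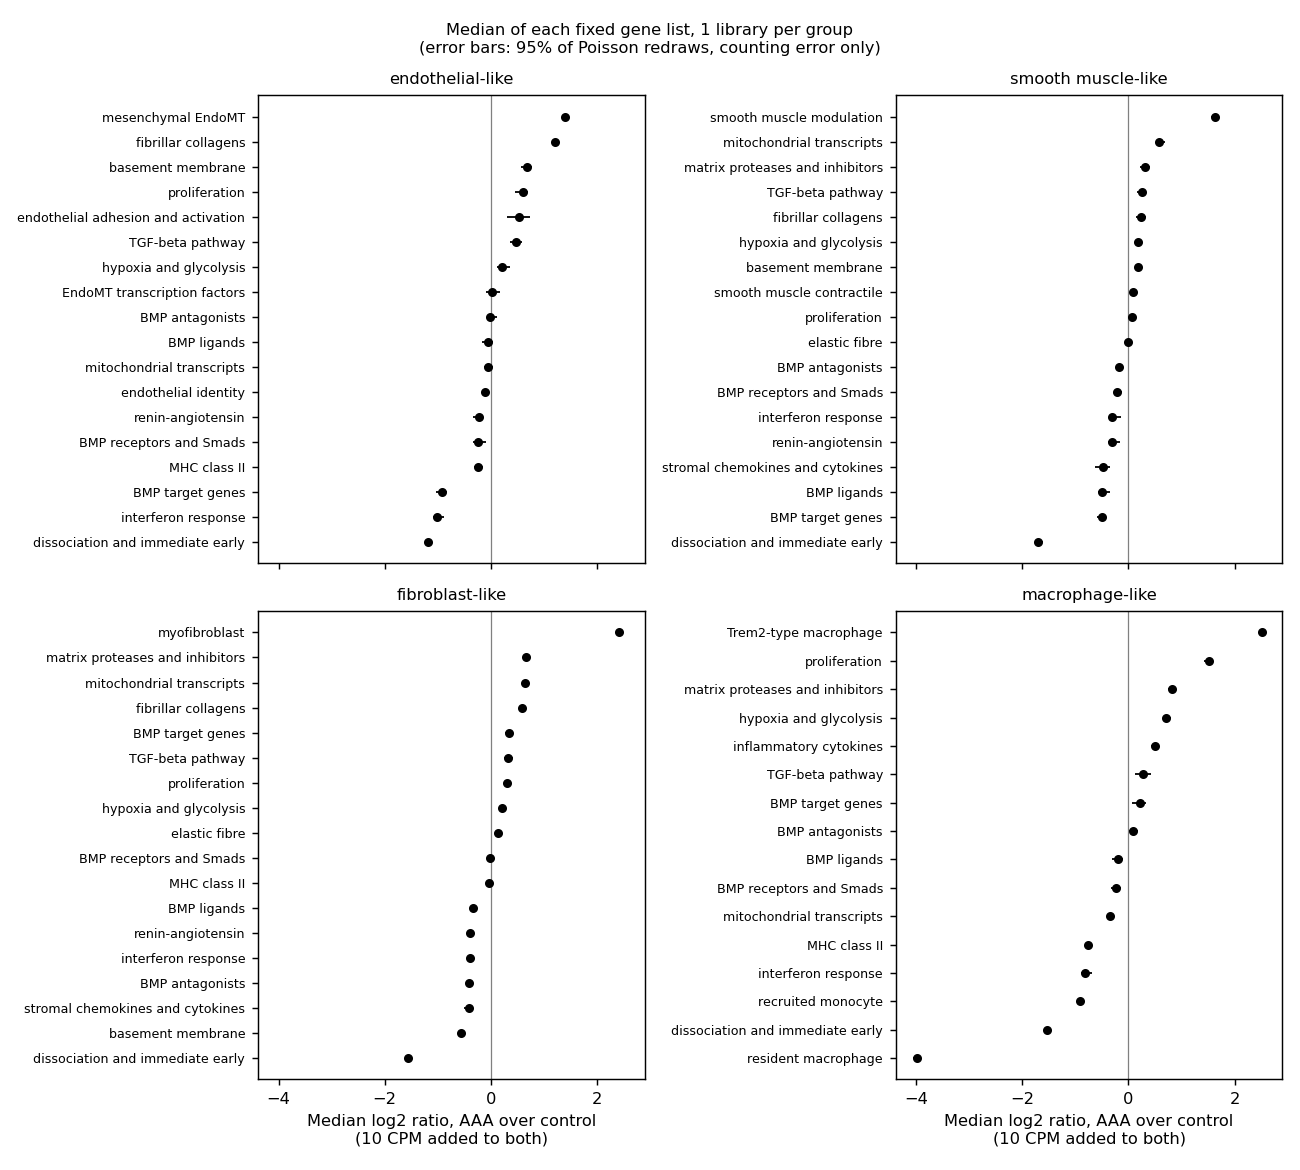
Median log2 ratio of AAA to control of each fixed gene list in the 4 main classes, with 95% of Poisson redraws as bars. Resident macrophage genes stand at -3.98 and Trem2-type genes at 2.52 in macrophage-like cells, and immediate early genes lie below 0 in every panel.

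Immediate early and dissociation genes, which respond to tissue handling within minutes to hours, were lower in the AAA library in the main classes, with medians of -1.19 (-1.22 to -1.12, percentile 0) in endothelial-like, -1.56 (-1.60 to -1.53, percentile 0) in fibroblast-like, -1.70 (-1.74 to -1.62, percentile 0) in smooth muscle-like and -1.53 (-1.57 to -1.50, percentile 0) in macrophage-like cells. The medians were -2.12 in Schwann-like, -1.82 in conventional dendritic-like, -1.33 in pericyte-like, -0.36 in lymphatic endothelial-like and -0.28 in T-like cells. Mitochondrial transcripts had medians of -0.05 (-0.14 to 0.04, percentile 30.67), 0.64 (0.59 to 0.69, percentile 100), 0.58 (0.53 to 0.69, percentile 100) and -0.35 (-0.40 to -0.28, percentile 3.02) in the 4 main classes in the same order. The median mitochondrial share of kept cells was 1.67% in the control and 3.20% in the AAA library. It is a low estimate, since mt-Co2 stood at 9.34 and 6.63 CPM in endothelial-like cells against 4488 and 4828 CPM of mt-Cytb.

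Among the smaller classes, conventional dendritic-like cells of the AAA library held more Ifitm1 (14.4 and 1855 CPM) and Cd72 (14.4 and 481 CPM) and less Cxcl9 (98.5 and 3.31 CPM). Lymphatic endothelial-like cells held more Npnt (5.43 and 327 CPM) and Ptx3 (10.9 and 234 CPM), a matrix ligand and a pentraxin, and less Ackr4 (300.2 and 24.3 CPM), the scavenger of homing chemokines, and their interferon response median was -0.90 (-1.24 to -0.73, percentile 0). Pericyte-like cells held more Thy1 (23.6 and 375 CPM) and less of the transcription factor Tbx5 (104 and 3.67 CPM). Schwann-like cells held more Vcam1 (28.1 and 349 CPM) and less Dusp15 (257 and 14.4 CPM) and Bcas1 (369 and 27.7 CPM), a pair of genes of myelinating cells. The Schwann-like levels compare control cells mostly of cluster 25 with AAA cells mostly of cluster 20. T-like cells held less Ccr7 (186 and 2.82 CPM), the homing chemokine receptor of naive T cells, which rested on 1 UMI in the AAA library, a ratio of 0.0152 (95% interval 0.000383 to 0.0852). Mgp stood at 116 and 5714 CPM in T-like and at 208 and 7045 CPM in lymphatic endothelial-like cells, possible free RNA beside the 84417 CPM of the unnamed AAA cluster 9. TGF-beta pathway medians were 0.86 in conventional dendritic-like, 0.59 in Schwann-like, -0.02 (-0.20 to 0.42, percentile 46.1) in T-like, -0.01 (-0.29 to 0.26, percentile 58.59) in lymphatic endothelial-like and -0.11 (-0.30 to 0.07, percentile 22.66) in pericyte-like cells.

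**Figure D5:**
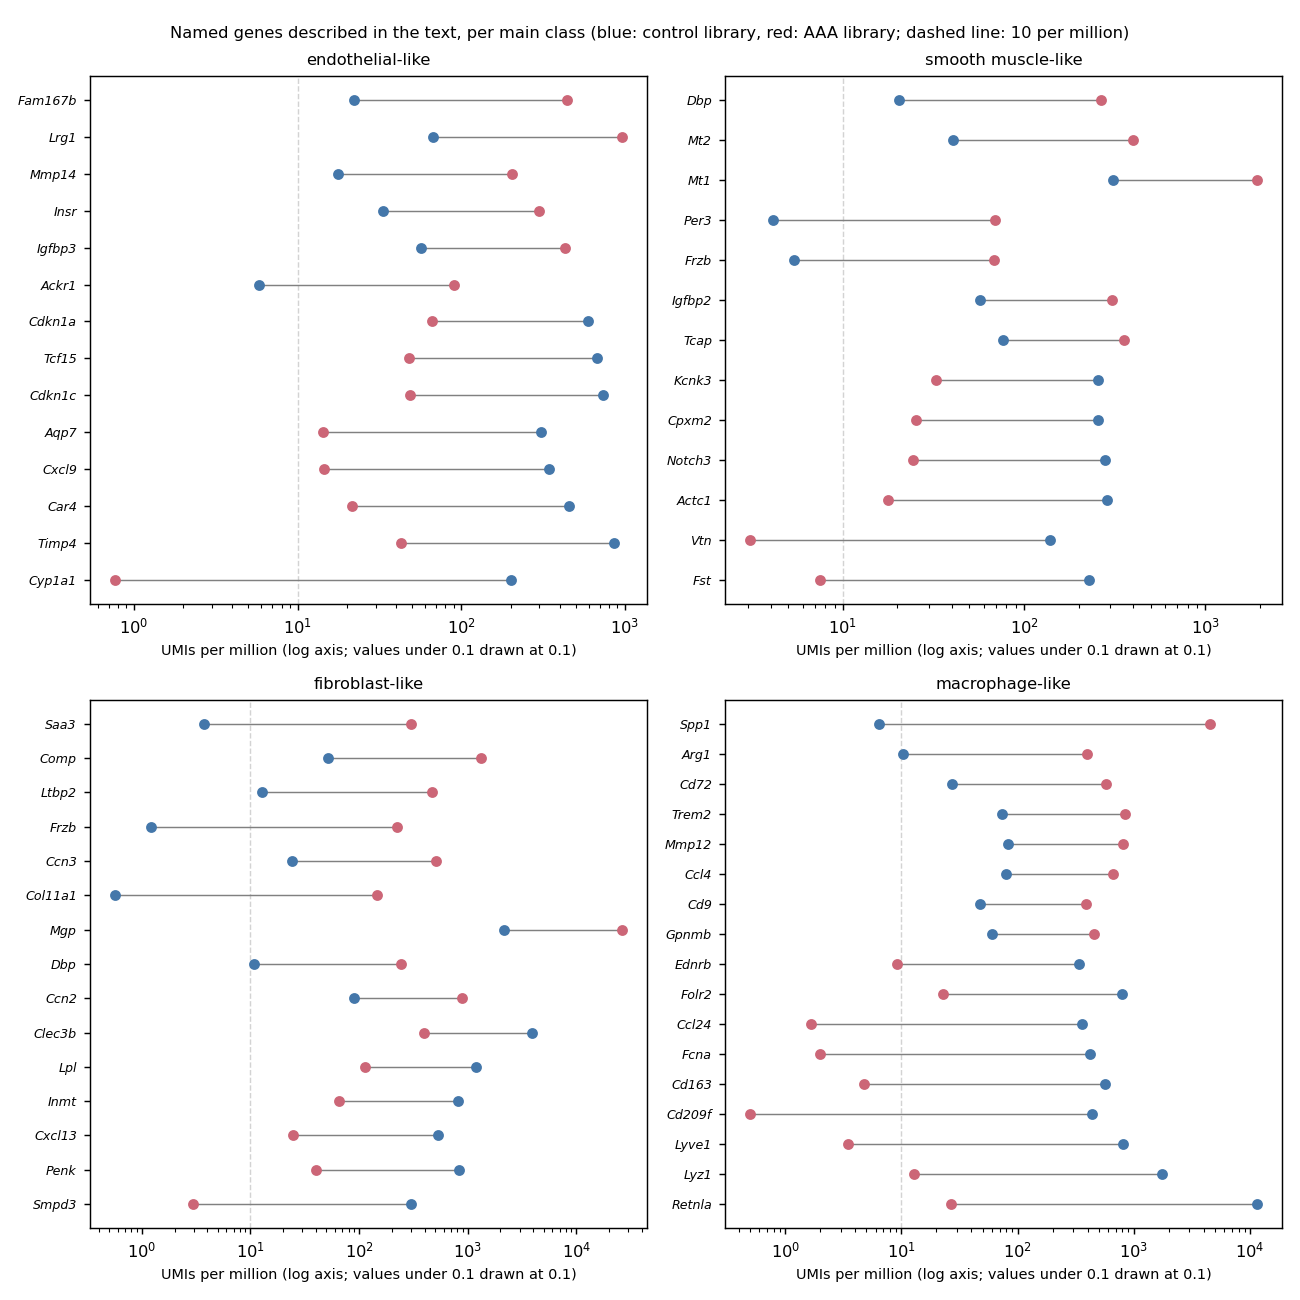
Levels in CPM of the named genes given in the text (log axis, values below 0.1 drawn at 0.1, dashed line at 10) in the control and AAA libraries for the 4 main classes. In macrophage-like cells Spp1 stands at 6.37 CPM in control and 4551 CPM in AAA, and Retnla at 11526 CPM and 27.0 CPM.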

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

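No paired analysis was possible because each group had 1 library, and for the same reason there was no value without a library. Naming by markers alone and the single-cluster values were chosen only after the results were seen, and the other alternatives were planned. All shares below are ratios of AAA to control, and all other values are log2 ratios unless stated. Among the 1048 other results on single genes, 813 stayed within their counting interval, 228 moved and 7 turned direction. Among 528 results on other lists, 314 stayed, 204 moved and 10 turned. Classes with few cells are limited by depth, and Bmp4 in macrophage-like cells was not separable from free RNA at this depth. The cause of the moves was not tested except where given.

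At resolution 0.5 the share ratio was 0.413 for endothelial-like, 1.39 for macrophage-like and 3.98 for smooth muscle-like cells. Bmp4 was -1.19 in endothelial-like cells, -0.054 in smooth muscle-like cells and -3.08 in the cluster matching cluster 17, which then held 295 control and 440 AAA cells. In smooth muscle-like cells Fst was 1.12, Cpxm2 1.95, Kcnk3 0.71 and Actc1 2.40. Endothelial-like BMP target genes were -1.35 and mesenchymal genes 0.98. The smooth muscle-like medians were 0.050 for BMP antagonists, 0.070 for contractile genes, 1.24 for modulation and 0.25 for stromal chemokines.

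At resolution 2.0 the endothelial-like share ratio was 0.320, with Bmp4 at -1.24 and mesenchymal genes at 1.82. Fibroblast-like fibrillar collagens were 0.63, macrophage-like recruited monocyte genes 0.15, smooth muscle-like contractile genes 0.026 and modulation 1.90. Bmp4 in the cluster matching cluster 11 was -0.48.

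With the libraries clustered separately the share ratios were 0.245 for endothelial-like, 0.737 for fibroblast-like, 1.26 for macrophage-like and 4.29 for smooth muscle-like cells.

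Without removal of doublets the share ratios were 0.346 for endothelial-like, 0.420 for fibroblast-like and 4.40 for smooth muscle-like cells. Bmp4 was 0.35 in endothelial-like cells, 0.15 in smooth muscle-like cells and -2.76 in the cluster matching cluster 17, which was unnamed and held 350 control and 481 AAA cells. In smooth muscle-like cells Cpxm2 was 1.02, Kcnk3 1.23 and Actc1 2.64. Endothelial-like mesenchymal genes were 1.84 and MHC class II 0.62, and fibroblast-like fibrillar collagens 0.65. Macrophage-like medians were -0.17 for BMP target genes, -0.18 for BMP antagonists, -0.17 for the TGF-beta pathway, -3.78 for resident and 2.23 for Trem2-type genes. Smooth muscle-like medians were 0.069 for BMP ligands, 0.12 for contractile genes, 1.26 for modulation, 0.22 for stromal chemokines and 0.16 for the interferon response. The share of control cells with Fn1, endothelial-like minus T-like, was -3.08 percentage points.

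With at most 10% mitochondrial UMIs the share ratio was 0.320 for endothelial-like and 1.17 for macrophage-like cells. With at least 200 genes per cell it was 0.413 for endothelial-like, 0.590 for fibroblast-like and 1.43 for macrophage-like cells. With at least 1000 genes it was 0.548 for fibroblast-like and 1.51 for macrophage-like cells.

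Scaling by median of ratios gave 1.36 for endothelial-like mesenchymal genes, 0.60 for fibroblast-like fibrillar collagens, 0.62 for inflammatory cytokines, -3.86 for resident and 2.64 for Trem2-type genes. The smooth muscle-like contractile median was then 0.23 and modulation 1.78. With cells weighted equally, Bmp4 was -0.58 in endothelial-like cells, 0.77 in fibroblast-like cells and -1.13 in cluster 17.

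A pseudocount of 1 gave -1.15 for endothelial-like BMP target genes, 2.91 for myofibroblast genes, 0.65 for inflammatory cytokines, -5.02 for resident, 2.64 for Trem2-type and 1.72 for modulation genes. A pseudocount of 50 gave -0.60 for endothelial-like BMP target genes, 1.12 for mesenchymal, 1.69 for myofibroblast, 0.34 for inflammatory, -3.12 for resident, 2.12 for Trem2-type and 0.97 for modulation genes.

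Without thinning, the share of AAA cells with a UMI, endothelial-like minus T-like, was 3.86 percentage points for Acta2, 2.93 for Tagln and 1.23 for Col1a1. With clusters named by markers alone the share ratio was 0.419 for endothelial-like and 1.47 for macrophage-like cells. Endothelial-like Bmp4 was then -1.23, BMP target genes -1.35 and mesenchymal genes 1.45, and macrophage-like inflammatory cytokines 0.55.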

Other observations

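The test lists of circadian and arterial genes were written before their tests, and so was the comparison of control cells by immediate early UMIs. The tests on the endothelial identity list, on the matching cluster at resolution 2.0 and on the Acta2 to Myh11 ratio, and the list of cartilage genes, were chosen only after the results were seen.

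Cartilage collagens stood higher in the AAA library. Col2a1, the main collagen of cartilage, stood at 0.134 and 62.5 CPM over all kept cells of the control and AAA libraries, a ratio of 465 (95% interval 277 to 851). Acan, the cartilage proteoglycan aggrecan, stood at 1.86 and 35.1 CPM. Sox9, a transcription factor of cartilage, was not higher, at 35.4 and 27.3 CPM, and Cnmd, another cartilage gene, was lower at 4.47 and 0.395 CPM. Cluster 9, with 0 control and 926 AAA cells, held 88.7% of the AAA library's Col2a1 UMIs, 90.7% of Col9a1, 71.8% of Col10a1 and 40.9% of Acan. Of the other cartilage genes it held 30.8% of the Sox9 UMIs, 24.5% of Col11a2, 6.90% of Matn3, 4.35% of Col9a2, 4.04% of Hapln1 and 0% of Cnmd. It also held 84417 CPM of Mgp, 10055 CPM of Eln and 6667 CPM of Spp1. It matched no named class, and cells of 1 library do not show whether it is a cell type.

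Cluster 18, with 12 control and 354 AAA cells and a median of 14466 UMIs in the AAA cells, led in endothelial markers. In its AAA cells Apln, a peptide of sprouting endothelium, stood at 564 CPM, the VEGF family member Pgf at 520.1 CPM, endothelin Edn1 at 410.5 CPM and the cycling gene Mki67 at 140.1 CPM. Cluster 19, with 41 control and 292 AAA cells, held 1921 CPM of the Wnt agonist Rspo3 and 3929 CPM of Apod.

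Bmp4 was lower in endothelial clusters 11 and 17 of the AAA library, with log2 ratios of -2.27 and -1.31 without a pseudocount. With the pseudocount of 10 CPM that the list medians used, they were -2.04 and -1.29. Dilution by free RNA would have lowered endothelial identity genes alike, but their medians were -0.091 (-0.18 to -0.03) in cluster 11 and 0.13 (0.03 to 0.25) in cluster 17, which speaks against it. Fewer arterial cells would have lowered arterial genes in cluster 17 as far as Bmp4, but their median over 8 genes was -0.21 (-0.31 to -0.07). Cells were grouped into cluster 17 by their expression, so similar arterial levels in both libraries may be partly built in. A different mix of arterial cells within the cluster was thus not excluded. Control cells of cluster 17 with more immediate early UMIs held 0.935 (0.878 to 0.995) times the Bmp4 of the rest. Bmp4 thus did not rise with immediate early UMIs between these cells. They all came from 1 library, so a handling response shared by the whole library could not be seen this way. Cluster 11 was not tested for it. A different mix of cells may account for part of the difference in cluster 11, since the matching cluster at resolution 2.0 had a log2 ratio of -0.48. The disease itself, a handling response of the whole library and the animals behind each library, whose number is not given, also remain open for cluster 17, since none of these can be tested with 1 library per group.

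Acta2 UMIs stood in most endothelial cells of the AAA library. In cluster 11 the ratio of Acta2 to Myh11 UMIs was 4.97 (4.44 to 5.57), near the 4.57 (3.64 to 5.80) of T-like cells, which is consistent with the free RNA found there, though smooth muscle-like cells had 3.47 (3.45 to 3.49), so the source of that RNA stays open. The ratio was 11.2 (8.66 to 14.8) in cluster 17 and 31.0 (28.2 to 34.2) in cluster 18, which speaks against free RNA as the only source there. Control cluster 17 had 11.9 (9.39 to 15.2), so its ratio was not particular to the AAA library. The highest ratio of any other AAA cluster with at least 50 cells and 500 CPM of Acta2 was 11.2. Mixing at such average levels could not give the ratio of cluster 18. Doublets with cells of a higher ratio within a cluster, or from smaller clusters, were not excluded. AAA cells of cluster 18 had a median of 14466 UMIs, against 3895 in cluster 11 and 6683 in cluster 17. After thinning, 76.7% of them had an Acta2 UMI, against 82.6% of T-like cells, though their CPM was higher (1912 against 1174). Acta2 expression in cluster 18 is thus left as a hypothesis.

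Dbp and Per3 were higher in the AAA library in smooth muscle-like and fibroblast-like cells. A different time of day of tissue collection is a candidate explanation, since genes that cycle with Dbp were higher and opposite-phase genes lower in 8 of 9 classes, T-like cells being the exception. Arntl, the opposite-phase activator, stood at 30.3 and 3.94 CPM in fibroblast-like and 24.7 and 1.95 CPM in smooth muscle-like cells, while Per1 was lower in the AAA library in 8 classes. Free RNA from fibroblast-like and smooth muscle-like cells was not excluded as a source of Dbp in the other classes. An effect of the disease on the clock remains open, and Dbp and Per3 had been seen when the list was written, so the opposite-phase genes are the independent part.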
